A study of Mus musculus with 122 samples.

How the data were processed

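Gene expression was measured with 2-colour Agilent arrays in mouse liver and liver tumors, 122 arrays in 20 groups. Per the labels, total RNA was amplified with an Agilent low-input linear method, the sample was labelled with Cy3 and a pool of C57BL/6 reference liver of both sexes with Cy5. The control group had 6 arrays, the 10 two-week groups 58 and the 9 tumor groups 58. Groups were taken from the labels, and each array is 1 sample.

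The deposited values are log2 ratios of red over green, made by the authors from background-subtracted signals with a correction for intensity. On the 1 array with scanner output (control replicate 6) the deposited value followed the log2 of red over green plus a smooth function of intensity, and was missing where either channel was not above 0. Per the file headers that scanner output is from Agilent Feature Extraction, with signals per channel in intensity units, ratios as log10, and marks for spots well above background. The sign of every deposited value was turned so that values are log2 sample over reference, except on control replicate 6, whose Y-linked and Xist signals lay in the opposite dyes. The deposited values covered 43379 spots, or 41174 probes after averaging 245 probes present on several spots, and 31482 probes had a gene symbol. Per gene the probe brightest in the reference channel of the scanned array stood for the gene. Missing values per array had a median of 7605 in control, 6312.5 in two-week and 9310 in tumor arrays, and 911 values (0.0211%) lay beyond 16. No scanner output was available for the other arrays, so their depth rests on the missing values, and the number of arrays limits the precision.

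Genes with a value in at least 90% of the arrays of a fit were tested, 18878 in the fit of livers, 17160 in the fit of livers and tumors, 15742 in the fit of oncogenes and 15426 in the fit of recipient sex. Each comparison was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with p-values adjusted by Benjamini and Hochberg within a comparison. A gene rose or fell at an adjusted p under 0.05, and counts are of such genes changed at least 2-fold. Two-week groups, the interactions of their transgenes and sex were fitted on livers with sex as a term. An interaction is the pair minus both singles plus control. Tumor comparisons were fitted on all arrays with array weights for 2 classes (liver 1.45, tumor 0.664) and a separate sex term in each class, where the sex is that of the recipient if the labels name one. The 4 oncogenes were fitted as additive terms over the 58 tumors, and recipient sex over 24 tumors labelled as from female donors.

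Gene lists were written before the data were examined, as were the groups, the comparisons, the rule for named genes and most alternatives. Of 36 lists 26 are described. Lists were tested with cameraPR of limma on z-scores with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and members are also counted with p-values adjusted over the list alone. Named genes are the 4 transgene symbols, with Xist and Y-linked genes for sex. To these come up to 4 passing members of a described list with the largest change (or up to 2 where none passed). Per comparison up to 5 passing genes each way with the largest change follow, with every sample of the group on 1 side of the mean of the other, except for interactions, sex and oncogenes. Over the 9 tumor comparisons up to 10 genes each way with the largest mean among those passing in all 9 were taken. Unnamed probes and clone names were left out. Some genes that these rules select are not reported here.

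Alternatives chosen with the design were centring each array on its median, quantile normalization, only probes well above background, probes with a value in every array, the mean of the probes of a gene, no sex term, the sex of the sample in place of the recipient, only the groups compared, equal weights, a robust prior with a trend, the replicate number as a block and leaving out samples or groups in turn. Alternatives chosen after the data were seen are named in the closing part. A count was taken as moved beyond 1.5 times. A result not called in either fit was counted as unchanged whatever its sign, and one called in either fit with the opposite sign in the other as turned. Every comparison was repeated on 100 random splits of its samples, on genes with a value in every array. The shared control arrays were simulated in 100 draws. The intensity trend of an array was a lowess fit with span 0.3.

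The fit was tested on simulated data with 11354 genes, 200 of them changed. A change of 2 on the log2 scale was recovered in 98% of genes for a two-week comparison, 92% for an interaction, 99% for a tumor comparison and 97% for an oncogene, and a change of 1 in 80%, 39%, 58% and 72%. Calls among unchanged genes numbered 8, 7, 4 and 14. Other tools were the data.table package, version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.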

Results

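Gene expression was measured on 122 two-colour Agilent arrays of mouse liver, each with 1 sample against a reference pool of both sexes. The 20 groups were 1 control group of livers with the hPAP marker transgene (n = 6), 10 groups of livers labelled with 2 weeks of expression of 1 or 2 oncogenes, and 9 groups of liver tumors. Letters give the transgenes as labelled, with B for beta-catenin, T for TGFalpha, M for c-Myc and H for H-ras. Each group held 6 samples except two-week HB (n = 4) and tumors M (n = 10). On the 1 array with scanner values, control replicate 6, 29994 of the 43379 spots lay well above background in both channels. Median missing values were 7605 per control, 6312.5 per two-week and 9310 per tumor array, and the number of arrays limits the precision. Changes below are log2 changes ± standard error, and a gene rose or fell only where its adjusted p in limma was under 0.05.

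Some arrays stood apart from their labels. On control replicate 6 the male-specific Y-linked transcripts lay in the opposite dye to the labelled one, with Ddx3y at 808 in green and 3.17 in red, so its deposited sign was kept while that of every other array was turned. As deposited it correlated over 15458 probes with the other 5 controls at 0.054 to 0.175 (negative after the turn), against 0.602 (median) between other livers. Xist and the Y-linked genes went against the labelled sex in two-week B replicate 1, two-week HT replicate 3 and tumor TM replicate 6. Of 58 two-week arrays, 37 had a median value more than 0.1 from 0, against 0 of 6 control arrays and 1 of 58 tumor arrays.

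The transgenes themselves were followed through the probes of the mouse genes, and the labels do not say whether a probe lies within a transgene. In two-week livers the symbol of a single transgene did not pass in its own group, with Ctnnb1 (-0.32 ± 0.21) in two-week B, Tgfa (-0.02 ± 0.28) in two-week T, Myc (0.25 ± 0.39) in two-week M (on the brightest Myc probe) and Hras (0.17 ± 0.18) in two-week H. In tumors, Myc probe A_52_P108346 read 4.95 ± 1.18 in tumors M (SD, n = 10), 4.21 ± 0.61 in BM and 3.55 ± 0.72 in TM, against -0.58 ± 0.47 in control livers (SD, n = 6 each). Means of two-week livers labelled with c-Myc stayed below these on that probe, at -0.26 ± 0.53 in M, -0.27 ± 0.50 in TM, -0.25 ± 1.29 in MH and -0.11 ± 0.77 in BM (SD, n = 6 each). Among them MH replicate 6 read 2.229 and the other 5 MH livers from -1.531 to -0.32. Tumors labelled HT read 5.23 ± 0.49, although their label names no c-Myc, and tumors labelled MH read 0.52 ± 0.79. The gap remained under another scaling, since after quantile normalization the 6 HT tumors lay between 3.67 and 5.30 and the 6 MH tumors between -0.20 and 1.01. The brightest Myc probe, A_51_P102096, which stands for the gene in the comparisons below, lay near 0 in the same tumors, at 0.18 in HT and -0.15 in M. Comparisons that use the labels of these 2 groups are written as tumors labelled HT and tumors labelled MH.

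**Figure D1:**
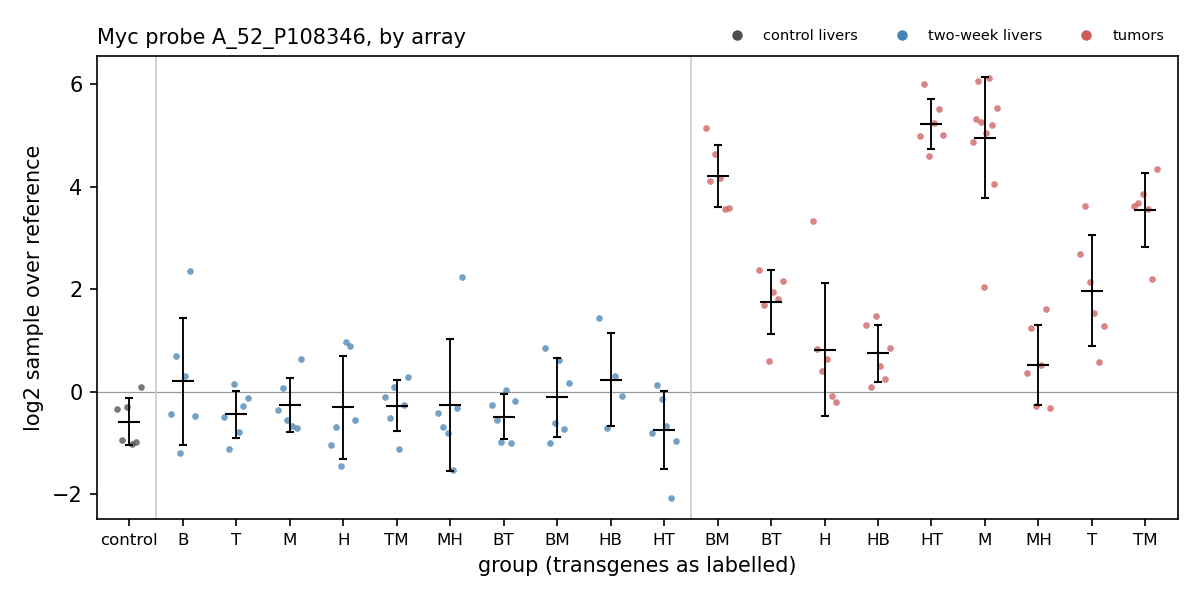
Log2 sample over reference of Myc probe A_52_P108346 in every array, by group as labelled, with the group mean and SD in black. Tumors labelled HT average 5.23, as high as tumors M at 4.95, and tumors labelled MH average 0.52.

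Sex was compared within livers, where the labels give males and females in each group. Male livers expressed more of the genes known to be male-biased in mouse liver, of which 10 of 12 rose, 11 adjusted over the list alone (camera adjusted p = 2.48e-32, adjusted p = 4.59e-11 with estimated correlation). Among them were the fatty acid hydroxylase Cyp4a12a (4.87 ± 0.24), the complement component C6 (3.50 ± 0.19) and the steroid dehydrogenase Hsd3b5 (3.12 ± 0.20). Of the female-biased list 16 of 16 fell, 16 adjusted over the list alone (camera adjusted p = 1.36e-58, adjusted p = 1.32e-08 with estimated correlation). Passing members included the sulfotransferase Sult3a1 (-10.39 ± 0.55). Y-linked Eif2s3y (8.02 ± 0.47) and Kdm5d (4.62 ± 0.45) were higher and the X-inactivation transcript Xist (-8.41 ± 0.57) was lower in males. Cell cycle genes were lower in males, since 9 of 29 fell, 1 rose and 13 fell adjusted over the list alone (camera adjusted p = 9.68e-05, adjusted p = 0.407 with estimated correlation). The largest included the replication helicase subunit Mcm6 (-1.14 ± 0.24) and the proliferation marker Mki67 (-0.81 ± 0.21). Beside them endothelial (mean -0.31), biliary (mean -0.49), stellate cell and fibroblast (mean -0.23) and lymphocyte (mean -0.19) genes were lower as lists (camera adjusted p = 9.68e-05, 0.0031, 0.0049 and 0.0478, adjusted p = 0.266, 0.163, 0.326 and 0.538 with estimated correlation), the last not called without control replicate 6 (mean -0.19, camera adjusted p = 0.0531), and erythroid (mean 0.32) genes were higher as a list (camera adjusted p = 0.0322, adjusted p = 0.0726 with estimated correlation). Of the bile acid list 5 of 17 rose, 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000538, adjusted p = 0.0316 with estimated correlation), led by the hydroxylase Cyp7b1 (1.44 ± 0.13). Between male and female livers 280 genes passed with at least a 2-fold change, 173 higher and 107 lower in males. Among these genes 61.8% were higher, against 47.2% of 464 after quantile normalization. The symbols Myc (0.15 ± 0.17), Ctnnb1 (0.11 ± 0.09), Tgfa (0.24 ± 0.12) and Hras (0.03 ± 0.08) did not pass.

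Each two-week group was compared with control. The interferon response list, antiviral genes induced by interferons, was called lower by camera in 9 of 10 comparisons, all but HB, and none of the 9 calls held with an estimated correlation. After quantile normalization those in TM, MH, BT, BM and HT ended and HB was called. Since the comparisons share 6 controls, unchanged groups and controls were drawn from shuffled liver residuals. On genes with a value in every array the list was lower in 10 of 10, against a simulated mean of 0.98 and as many in 1 of 100 draws. With only 3 male or 3 female controls it was lower in 6 and 8 of 10. The Kupffer cell and macrophage list was called lower in 6 of 10 (0 without control replicate 6). Of 100 draws 1 gave as many calls for biliary and 3 for macrophage genes, uncorrected over the lists. For lymphocyte, cholesterol, Wnt, amino acid and endothelial genes 19 to 55 did, leaving chance open. With only the groups compared and no sex term, the counts below shrank to 0 to 118.

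In two-week B livers, labelled with beta-catenin, interferon genes were lower: 4 of 14 fell, 5 adjusted over the list alone (camera adjusted p = 1.18e-07, adjusted p = 0.327 with estimated correlation). They included the RNA sensor cofactor Dhx58 (-1.28 ± 0.21), at 0.02 with the mean of its probes. Of the Kupffer cell and macrophage list, markers of the resident macrophages, 2 of 14 fell, 2 adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.925 with estimated correlation), not called without control replicate 6 (mean -0.20 from -0.40, camera adjusted p = 0.107). Also cholesterol synthesis (mean 0.69) genes were higher as a list (camera adjusted p = 0.00013, adjusted p = 0.76 with estimated correlation). Of the Wnt targets, Rhbg (0.90 ± 0.28) rose while Rnf43 (-0.86 ± 0.23) and Notum (-0.73 ± 0.19) fell (camera adjusted p = 0.287). Rhbg (0.92) did not pass without control replicate 6, nor Rhbg (0.85) without two-week B replicate 1. The embryonic globin Hbb-bh1 (4.05 ± 0.72) and the matrix linker Hapln1 (7.58 ± 1.80) rose, and the adhesion molecule Cdh1 (-2.32 ± 0.56) and the guanylate-binding protein Gbp4 (-2.80 ± 0.56) fell. In two-week B livers (n = 6) 418 genes passed with at least a 2-fold change against control (n = 6), 122 higher and 296 lower. Thus 29.2% were higher, against 13.2% of 657 with centring and 6.66% of 1712 after quantile normalization. For two-week B livers the median of all genes moved by -0.19 under centring and -0.28 under quantile normalization.

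Two-week T livers are labelled with TGFalpha, a ligand of the EGF receptor. Of the interferon list 4 of 14 fell, 5 adjusted over the list alone (camera adjusted p = 4.84e-05, adjusted p = 0.957 with estimated correlation). Among them were Ifit3 (-0.92 ± 0.18) and Gbp2 (-0.83 ± 0.22). E-cadherin Cdh1 (-3.52 ± 0.56) and the fatty acid hydroxylase Cyp4a14 (-2.90 ± 0.55) fell, and the phosphatase Dusp16 (3.02 ± 0.55), the acute phase protein Crp (2.54 ± 0.58) and Hbb-bh1 (3.38 ± 0.72) rose. ERK pathway genes, which report signalling below the receptor, did not pass, and the largest values were Phlda1 (-1.10 ± 0.47) and Egr1 (1.02 ± 0.69) (camera adjusted p = 0.928). In two-week T livers (n = 6) 425 genes passed with at least a 2-fold change against control (n = 6), 43 higher and 382 lower. That is, 10.1% were higher, against 25.3% after quantile normalization.

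Two-week M livers are labelled with c-Myc, and no Myc probe bore this out. Interferon genes were lower here as well: 4 of 14 fell, 5 adjusted over the list alone (camera adjusted p = 3.41e-05, adjusted p = 0.998 with estimated correlation). They included Ifit3 (-1.06 ± 0.18) and Gbp2 (-1.0 ± 0.22). Of the cell cycle genes none passed, and the largest values were Ccne2 (1.08 ± 0.50) and Mki67 (-0.86 ± 0.48) (camera adjusted p = 0.86). The growth regulator Deptor (-2.69 ± 0.39) and Cdh1 (-4.00 ± 0.56) fell, and Dusp16 (3.27 ± 0.55), Crp (3.18 ± 0.58) and the reductase Cbr1 (1.85 ± 0.36) rose. In two-week M livers (n = 6) 199 genes passed with at least a 2-fold change against control (n = 6), 32 higher and 167 lower. In all, 16.1% were higher, against 33.9% of 115 with centring and 71.9% of 367 after quantile normalization. For two-week M livers the median of all genes moved by 0.15 under quantile normalization.

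Two-week H livers are labelled with H-ras, a small GTPase upstream of the ERK kinases. There 4 of 14 fell, 5 adjusted over the list alone (camera adjusted p = 3.54e-05, adjusted p = 0.926 with estimated correlation) in the interferon list, with Dhx58 (-1.10 ± 0.21). Macrophage genes were lower, since 2 of 14 fell, 2 adjusted over the list alone (camera adjusted p = 0.00181, adjusted p = 0.926 with estimated correlation), not called without control replicate 6 (mean -0.40 from -0.61, camera adjusted p = 0.0789). They included Cd5l (-1.49 ± 0.34). ERK pathway genes did not pass, the largest values being Etv5 (1.35 ± 1.75) and Egr1 (1.27 ± 0.69). Outside the lists Tmem54 (4.51 ± 1.08) and Dusp16 (2.82 ± 0.55) rose, and Gbp4 (-2.92 ± 0.56) and Deptor (-2.39 ± 0.39) fell. In two-week H livers (n = 6) 451 genes passed with at least a 2-fold change against control (n = 6), 50 higher and 401 lower. Of them 11.1% were higher, against 30.7% of 1053 after quantile normalization.

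Two-week TM livers changed in few single genes. The lectin-like receptor Clec2d (1.92 ± 0.41) rose, and keratin Krt6a (-3.27 ± 0.60) and the transaminase Kyat1 (-0.82 ± 0.17) fell. Clec2d (1.73) and Kyat1 (-0.80) did not pass without control replicate 6. In the interferon list 0 of 14 passed in limma, 5 fell adjusted over the list alone, and at unadjusted p under 0.05 0 lay higher and 5 lower (camera adjusted p = 4.19e-05, adjusted p = 0.66 with estimated correlation). Also endothelial (mean 0.27) and biliary (mean 0.20) genes were higher as lists (camera adjusted p = 0.0116 and 0.0116, adjusted p = 0.799 and 0.66 with estimated correlation), and macrophage (mean -0.45) genes were lower as a list (camera adjusted p = 0.0116, adjusted p = 0.799 with estimated correlation). In two-week TM livers (n = 6) 6 genes passed with at least a 2-fold change against control (n = 6), 1 higher and 5 lower. Of these 16.7% were higher, against 33.3% with centring, 44.4% of 18 after quantile normalization and 0% of 3 with the intensity trend removed. For two-week TM livers the median of all genes moved by 0.12 under centring and 0.20 under quantile normalization and the count was 10 without control replicate 6 and 15 with the array score as a term.

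In two-week MH livers Hbb-bh1 (3.51 ± 0.72) rose. The T cell receptor Tcra (-3.67 ± 0.85) fell. Of the interferon list 1 of 14 fell, 5 adjusted over the list alone (camera adjusted p = 0.00422, adjusted p = 0.861 with estimated correlation), the member being Ifit3 (-0.84 ± 0.18). Of the macrophage list 1 of 14 fell, 4 adjusted over the list alone (camera adjusted p = 0.00187, adjusted p = 0.861 with estimated correlation). Neither list was called without control replicate 6 (macrophage mean -0.51 from -0.72 and interferon mean -0.37 from -0.50, camera adjusted p = 0.0504 each). Ifit3 (-0.72) did not pass without control replicate 6. Among other cells lymphocyte (mean -0.64) genes were lower as a list (camera adjusted p = 0.00578, adjusted p = 0.861 with estimated correlation). In two-week MH livers (n = 6) 140 genes passed with at least a 2-fold change against control (n = 6), 4 higher and 136 lower. Among these genes 2.86% were higher, against 27% with centring, 79% of 795 after quantile normalization and 14% of 86 with the intensity trend removed. For two-week MH livers the median of all genes moved by 0.14 under centring and 0.26 under quantile normalization and the count was 55 without control replicate 6 and 299 with the array score as a term. Of 100 splits of the samples 9, the real one included, gave as many genes.

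Two-week BT livers gained markers of bile duct and progenitor cells, of which 4 of 13 rose, 6 adjusted over the list alone (camera adjusted p = 0.00169, adjusted p = 0.348 with estimated correlation). These were the transcription factor Sox9 (1.16 ± 0.29), the adhesion molecule Epcam (1.11 ± 0.29), osteopontin Spp1 (1.06 ± 0.22) and the tight junction protein Cldn7 (0.87 ± 0.21). Amino acid breakdown was lower: 4 of 17 fell, 5 adjusted over the list alone (camera adjusted p = 0.00665, adjusted p = 0.551 with estimated correlation), not called after quantile normalization (mean -0.31, camera adjusted p = 0.0844) and with the intensity trend removed (mean -0.25, camera adjusted p = 0.104). Members included the methyltransferase Gnmt (-1.82 ± 0.38). Interferon genes were lower too, since 2 of 14 fell, 2 adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.551 with estimated correlation), led by Gbp2 (-1.23 ± 0.22). The mouse symbols of both transgenes fell, Ctnnb1 (-0.95 ± 0.21) and Tgfa (-0.95 ± 0.28). Tgfa (-0.89) did not pass without control replicate 6, nor Tgfa (-0.83) without two-week BT replicate 5. In two-week BT livers (n = 6) 546 genes passed with at least a 2-fold change against control (n = 6), 239 higher and 307 lower. Thus 43.8% were higher, against 55.7% with centring, 66.7% of 3 after quantile normalization and 59.6% with the intensity trend removed. The count was 327 without control replicate 6, 256 without two-week BT replicate 5 and 282 with the array score as a term.

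In two-week BM livers the ammonium transporter Rhbg (1.03 ± 0.28) was the Wnt target that passed, and of that list 1 of 19 rose, 1 adjusted over the list alone (camera adjusted p = 0.0195, adjusted p = 0.674 with estimated correlation), not called after quantile normalization (mean 0.54, camera adjusted p = 0.14), with the intensity trend removed (mean 0.29, camera adjusted p = 0.0534) and with the array score as a term (mean 0.28, camera adjusted p = 0.0525). Rhbg (1.06) did not pass without control replicate 6. Cholesterol synthesis stood higher although 0 of 15 passed in limma, 6 rose adjusted over the list alone, and at unadjusted p under 0.05 8 lay higher and 0 lower (camera adjusted p = 0.000394, adjusted p = 0.674 with estimated correlation). Interferon genes were lower, as 2 of 14 fell, 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.675 with estimated correlation), not called without control replicate 6 (mean -0.21 from -0.35, camera adjusted p = 0.0904). The phosphatase Dusp16 (3.00 ± 0.55) and the calcineurin regulator Rcan2 (1.72 ± 0.36) rose, and Krt6a (-2.80 ± 0.60) and Cdh1 (-2.51 ± 0.56) fell. Also macrophage (mean -0.44) genes were lower as a list (camera adjusted p = 0.0101, adjusted p = 0.675 with estimated correlation), and biliary (mean 0.29) genes were higher as a list (camera adjusted p = 0.0481, adjusted p = 0.674 with estimated correlation). In two-week BM livers (n = 6) 89 genes passed with at least a 2-fold change against control (n = 6), 35 higher and 54 lower. That is, 39.3% were higher, against 66.2% with centring and 82.7% of 352 after quantile normalization. For two-week BM livers the median of all genes moved by 0.13 under centring and 0.19 under quantile normalization and the count was 57 without control replicate 6.

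Two-week HB livers had 4 samples. Biliary Sox9 (1.43 ± 0.33) rose, and Gnmt (-1.54 ± 0.43) fell. The oxidase Duox2 (2.56 ± 0.58) and Dusp16 (2.83 ± 0.61) rose. Duox2 (1.73), Dusp16 (2.19) and Gnmt (-1.46) did not pass without two-week HB replicate 2, nor Gnmt (-1.30) without two-week HB replicate 4. In two-week HB livers (n = 4) 641 genes passed with at least a 2-fold change against control (n = 6), 137 higher and 504 lower. In all, 21.4% were higher, against 48.4% with centring, 80% of 5 after quantile normalization and 40.2% with the intensity trend removed. For two-week HB livers the median of all genes moved by 0.17 under centring and 0.14 under quantile normalization. The count was 1909 without two-week HB replicate 1, 60 without two-week HB replicate 2, 1530 without two-week HB replicate 3, 356 without control replicate 6 and 71 with the array score as a term. Of 100 splits of the samples 5, the real one included, gave as many genes.

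Two-week HT livers showed lower interferon genes, of which 3 of 14 fell, 6 adjusted over the list alone (camera adjusted p = 0.000267, adjusted p = 0.678 with estimated correlation). The largest included Gbp2 (-1.30 ± 0.22). Macrophage genes were lower, as 2 of 14 fell, 3 adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.773 with estimated correlation), not called without control replicate 6 (mean -0.33 from -0.55, camera adjusted p = 0.0934). Beside them endothelial (mean 0.29) genes were higher as a list (camera adjusted p = 0.0405, adjusted p = 0.773 with estimated correlation). Keratin Krt23 (1.75 ± 0.36), the acute phase protein Orm3 (1.83 ± 0.44) and Dusp16 (2.94 ± 0.55) rose, and Cdh1 (-2.93 ± 0.56) and Gbp4 (-2.54 ± 0.56) fell. In two-week HT livers (n = 6) 167 genes passed with at least a 2-fold change against control (n = 6), 61 higher and 106 lower. Of them 36.5% were higher, against 66.2% with centring, 92.4% after quantile normalization and 47.2% with the intensity trend removed. For two-week HT livers the median of all genes moved by 0.12 under centring and 0.18 under quantile normalization and the count was 62 without control replicate 6.

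All 6 pairs of the 4 oncogenes were made, so each pair was tested for a change that differs from the sum of its singles. A positive interaction means that the pair lay above that sum. Because each interaction subtracts 2 singles and adds control once, a change shared by all two-week livers returns in it with the opposite sign. In all 6 interactions 168 genes passed as positive and 37 as negative, and 148 of these 205 lay on the opposite side of control in all 10 two-week groups. E-cadherin Cdh1 had interactions from 3.06 to 6.65 and changes against control from -4.00 to -0.17. The interactions share their control arrays, and in draws of unchanged groups, taking as many genes from each interaction, 28.5 genes recurred on average and 158 at most, against 244 on the same genes, and 20.3 and 175 of these lay opposite in all 10. This look was chosen after the interactions were seen. With the mean of the probes the list calls below ended for interferon in TM, BT and HB, Wnt targets in BM and cholesterol in HB. Arrays of some pairs also spread along 1 gene axis within groups. On it the 4 groups B, T, M and H averaged 0.65, 0.59, 0.67 and 0.74. MH lay with them (0.64, from 0.41 to 0.87), and BT, HB, HT, BM and TM averaged -1.33, -0.98, -0.60, -0.40 and -0.13.

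**Figure D2:**
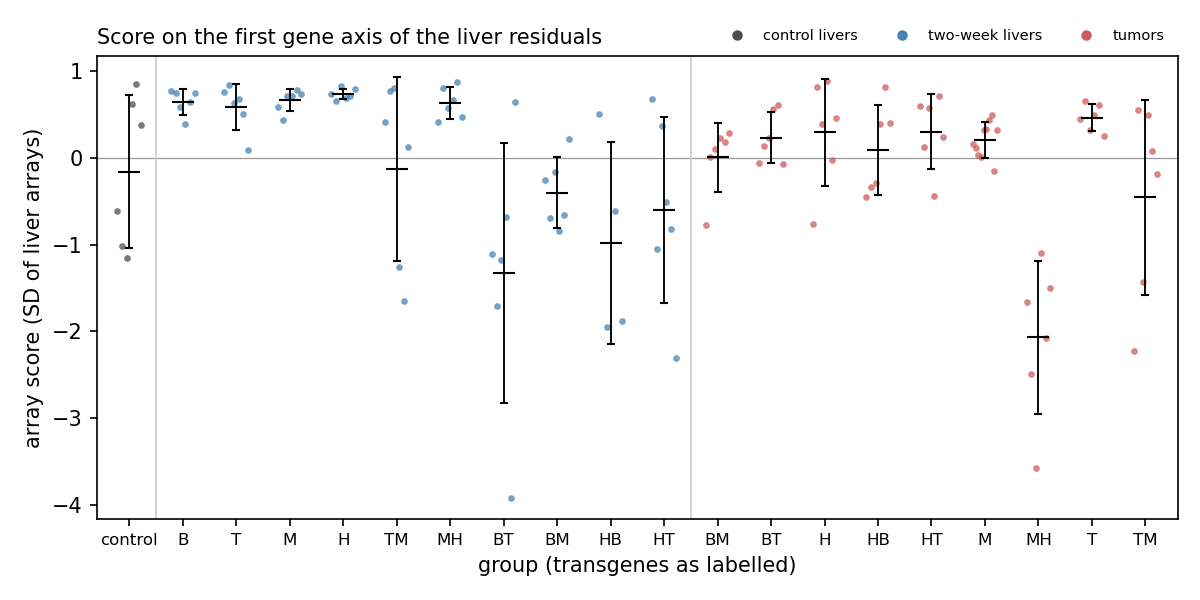
Score of every array on the first gene axis of the liver residuals, in units of the liver SD, by group as labelled, with the group mean and SD in black. Two-week BT livers range from -3.92 to 0.65 and tumors labelled MH from -3.58 to -1.10.

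In the TM interaction Cdh1 (5.63 ± 0.79), Deptor (3.85 ± 0.55) and Cyp4a14 (4.05 ± 0.78) were positive, and Crp (-4.63 ± 0.82) and Dusp16 (-4.32 ± 0.77) were negative. For the interferon list 2 of 14 were positive, 4 adjusted over the list alone (camera adjusted p = 0.00449, adjusted p = 0.899 with estimated correlation). These included Ifit3 (1.43 ± 0.25). For the TM interaction 643 genes passed with at least a 2-fold value, 481 positive and 162 negative. Of these 74.8% were positive, against 55.2% after quantile normalization.

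The MH interaction was positive for Cdh1 (6.65 ± 0.79), Gbp4 (4.09 ± 0.79) and Deptor (3.92 ± 0.55) and negative for Crp (-5.41 ± 0.82) and Dusp16 (-5.27 ± 0.77). Of the interferon list 4 of 14 were positive, 6 adjusted over the list alone (camera adjusted p = 0.000422, adjusted p = 0.963 with estimated correlation). For the MH interaction 474 genes passed with at least a 2-fold value, 363 positive and 111 negative. In the MH interaction the count was 850 after quantile normalization.

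For the BT interaction, among cholesterol synthesis genes 8 of 15 were negative, 8 adjusted over the list alone (camera adjusted p = 0.000202, adjusted p = 0.983 with estimated correlation). They included Nsdhl (-2.94 ± 0.65), Fdps (-2.38 ± 0.51), Cyp51 (-1.94 ± 0.46) and Msmo1 (-1.69 ± 0.44). Of the interferon list 3 of 14 were positive, 4 adjusted over the list alone (camera adjusted p = 0.00537, adjusted p = 0.983 with estimated correlation), led by Dhx58 (1.82 ± 0.29). The pericentral Wnt targets Lgr5 (1.74 ± 0.50), Tbx3 (1.74 ± 0.55) and Glul (1.57 ± 0.47), the glutamine synthetase, were positive and Cyp2e1 (-1.12 ± 0.40) was negative. Cyp2e1 (-0.72) and Tbx3 (1.41) did not pass without two-week BT replicate 5. The hypoxia factor Epas1 (3.60 ± 0.76) was positive and Hbb-bh1 (-4.83 ± 0.99) negative. For the BT interaction 3088 genes passed with at least a 2-fold value, 1631 positive and 1457 negative. Among these genes 52.8% were positive, against 70.2% with centring and 78.3% after quantile normalization. In the BT interaction the median of all genes moved by 0.21 under centring and 0.33 under quantile normalization and the count was 1213 with the array score as a term.

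The BM interaction was positive for Wnt targets, of which 3 of 19 were positive, 7 adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.537 with estimated correlation), not called without control replicate 6 (mean 0.48 from 0.55, camera adjusted p = 0.0954). They were Tbx3 (2.10 ± 0.55), Lgr5 (1.74 ± 0.50) and Rnf43 (1.32 ± 0.33). Interferon genes followed, as 4 of 14 were positive, 6 adjusted over the list alone (camera adjusted p = 3.18e-05, adjusted p = 0.537 with estimated correlation), including the RNA sensor Ddx58 (2.07 ± 0.47), at -0.54 with the mean of its probes. For the BM interaction 1070 genes passed with at least a 2-fold value, 737 positive and 333 negative. Thus 68.9% were positive, against 88.6% with centring and 86.7% of 2489 after quantile normalization. In the BM interaction the median of all genes moved by 0.24 under centring and 0.34 under quantile normalization and the count was 316 with the array score as a term.

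Cholesterol genes were also negative in the HB interaction, where 6 of 15 were negative, 8 adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.979 with estimated correlation). Members were Nsdhl (-2.95 ± 0.69) and Fdps (-2.12 ± 0.54), the latter at 0.52 with the mean of its probes. Macrophage genes were positive, since 3 of 14 were positive, 4 adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.979 with estimated correlation), not called without control replicate 6 (mean 0.50 from 0.69, camera adjusted p = 0.117) and not called with the intensity trend removed (mean 0.81, camera adjusted p = 0.0769). They included Cd5l (1.81 ± 0.52) and Csf1r (1.35 ± 0.40). Beside them endothelial (mean 0.67) genes were higher as a list (camera adjusted p = 0.0175, adjusted p = 0.979 with estimated correlation), not called without control replicate 6 (mean 0.56, camera adjusted p = 0.101). Of the interferon list 4 of 14 were positive, 4 adjusted over the list alone (camera adjusted p = 0.00366, adjusted p = 0.979 with estimated correlation), led by Dhx58 (1.93 ± 0.31), at -0.12 with the mean of its probes. For the HB interaction 2869 genes passed with at least a 2-fold value, 1276 positive and 1593 negative. That is, 44.5% were positive, against 75% with centring, 85.3% after quantile normalization and 58.7% with the intensity trend removed. In the HB interaction the median of all genes moved by 0.35 under centring and 0.42 under quantile normalization. The count was 4358 without two-week HB replicate 1, 1351 without two-week HB replicate 2 and 46 with the array score as a term.

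The HT interaction was positive for the Wnt targets Lgr5 (1.85 ± 0.50) and Glul (1.52 ± 0.47) and for the interferon genes Ifit3 (1.32 ± 0.25) and Dhx58 (1.10 ± 0.29). It was negative for the cholesterol genes Nsdhl (-2.01 ± 0.65) and Fdps (-1.88 ± 0.51). Neither list was called (interferon camera adjusted p = 0.0558). For the HT interaction 1709 genes passed with at least a 2-fold value, 1017 positive and 692 negative. In the HT interaction the median of all genes moved by 0.12 under quantile normalization and the count was 905 with the array score as a term.

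Tumors, alone labelled with a recipient, were compared with two-week livers of the same label and as a whole with control. Tumor stage and recipient are not separated. In all 9 tumor comparisons 202 genes rose and 275 fell, against 0.000756 and 0.000706 if calls were independent. All share a fit, so calls are not independent. The largest mean rises over the 9 were the aldose reductase family member Akr1b7 (6.18), the asparagine synthetase Asns (6.17), alpha-fetoprotein Afp (5.98), Psrc1 (5.88), Esm1 (5.84), Chil3 (5.52), the desaturase Scd2 (5.43) and the serine synthesis enzymes Psat1 (5.32) and Phgdh (5.24). The largest mean falls were in the major urinary proteins Mup6 (-7.48), Mup5 (-6.26) and Mup1 (-5.17), the pseudogene Serpina4-ps1 (-5.94), the anion transporter Slco1a1 (-5.71) and the Wnt agonist Rspo1 (-5.29).

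Against control, tumors expressed more of the fetal liver and oncofetal list, of which 9 of 14 rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 5.07e-11, adjusted p = 1.86e-05 with estimated correlation). Passing members included Afp (6.90 ± 0.39), Scd2 (5.38 ± 0.29) and the proteoglycan Gpc3 (3.98 ± 0.39). Cell cycle genes were higher, as 17 of 26 rose and 1 fell, 17 and 1 adjusted over the list alone (camera adjusted p = 9.09e-06, adjusted p = 0.359 with estimated correlation). The largest included Nusap1 (2.71 ± 0.49) and Mki67 (2.03 ± 0.37). Of the male-biased list 11 of 12 fell, 11 adjusted over the list alone (camera adjusted p = 2.62e-12, adjusted p = 0.000127 with estimated correlation). These included Slco1a1 (-5.70 ± 0.36) and Cyp7b1 (-4.47 ± 0.35). Beside them urea cycle (mean -1.47) and endothelial (mean -0.72) genes were lower as lists (camera adjusted p = 2.59e-09 and 0.0212, adjusted p = 0.0967 and 0.557 with estimated correlation), the latter not called without control replicate 6 (mean -0.60, camera adjusted p = 0.0624), and neutrophil (mean 2.47) genes were higher as a list (camera adjusted p = 0.0113, adjusted p = 0.216 with estimated correlation). Between tumors (n = 58) and control (n = 6) 2724 genes passed with at least a 2-fold change, 1269 higher and 1455 lower.

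**Figure D3:**
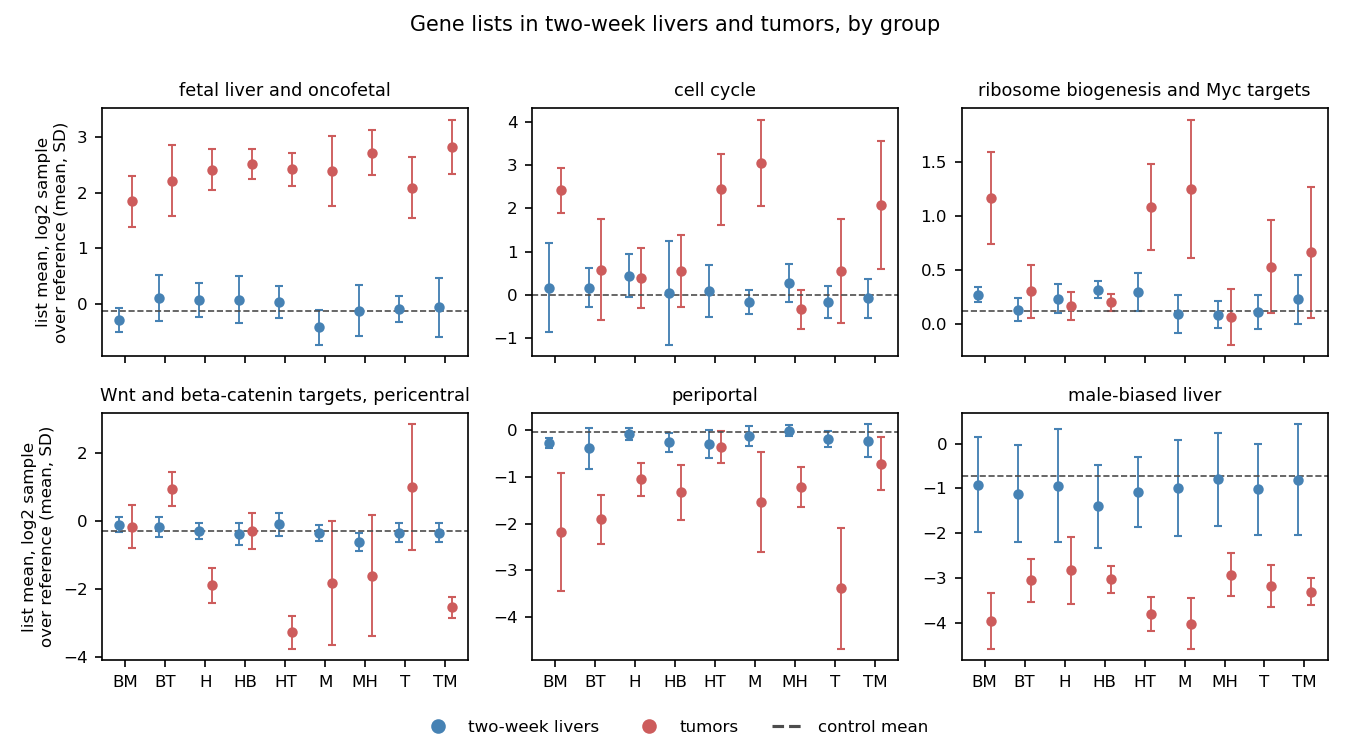
Mean over the members of 6 gene lists (log2 sample over reference) in two-week livers and tumors of each label, with the SD between arrays and the control mean as a dashed line. The fetal list lies between 1.85 and 2.83 in the 9 tumor groups and the Wnt list between -3.27 in tumors labelled HT and 1.00 in tumors T.

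Tumors BM, with beta-catenin and c-Myc, expressed cell cycle genes, of which 22 of 26 rose and 1 fell, 23 and 1 adjusted over the list alone (camera adjusted p = 3.76e-07, adjusted p = 0.282 with estimated correlation). Among them were the spindle protein Tpx2 (3.57 ± 0.76) and Mki67 (3.13 ± 0.59). Of the ribosome biogenesis and Myc target list 16 of 28 rose, 19 adjusted over the list alone (camera adjusted p = 3.76e-07, adjusted p = 0.248 with estimated correlation), with nucleophosmin Npm1 (2.03 ± 0.26). Also periportal (mean -1.90) and endothelial (mean -1.46) genes were lower as lists (camera adjusted p = 8.25e-06 and 0.00108, adjusted p = 0.224 and 0.394 with estimated correlation), and non-hepatic glycolysis (mean 1.54) and neutrophil (mean 2.53) genes were higher as lists (camera adjusted p = 1.58e-07 and 0.0496, adjusted p = 0.0243 and 0.328 with estimated correlation). In tumors BM (n = 6) 3997 genes passed with at least a 2-fold change against two-week BM livers (n = 6), 1838 higher and 2159 lower. In all, 46% were higher, against 29.7% after quantile normalization. For tumors BM the median of all genes moved by -0.13 under centring and -0.22 under quantile normalization.

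Tumors BT gained Wnt targets, of which 4 of 19 rose, 3 adjusted over the list alone (camera adjusted p = 0.0261, adjusted p = 0.712 with estimated correlation), not called with the mean of the probes (mean 0.92, camera adjusted p = 0.063). Passing members included Rhbg (3.00 ± 0.62) and Tnfrsf19 (2.40 ± 0.65). Stress genes were higher, as 8 of 12 rose, 8 adjusted over the list alone (camera adjusted p = 5.52e-05, adjusted p = 0.0241 with estimated correlation). The largest included Asns (5.24 ± 0.51), Atf3 (2.23 ± 0.40) and Xbp1 (2.22 ± 0.41). Also periportal (mean -1.52), endothelial (mean -1.89), macrophage (mean -1.64), stellate cell and fibroblast (mean -1.87) and lymphocyte (mean -0.84) genes were lower as lists (camera adjusted p = 7.9e-05, 1.3e-06, 6.26e-05, 0.000418 and 0.0255, adjusted p = 0.418, 0.333, 0.418, 0.479 and 0.479 with estimated correlation). The symbols Myc (1.96 ± 0.48), Tgfa (1.72 ± 0.36) and Hras (0.99 ± 0.23) rose. In tumors BT (n = 6) 3551 genes passed with at least a 2-fold change against two-week BT livers (n = 6), 1737 higher and 1814 lower. For tumors BT the median of all genes moved by -0.11 under quantile normalization.

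In tumors H the ERK pathway list was higher, as 9 of 16 rose, 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000571, adjusted p = 0.206 with estimated correlation). These included Egr1 (3.26 ± 0.76) and the feedback inhibitor Spry2 (2.68 ± 0.59). Bile acid synthesis was lower: 14 of 17 fell, 14 adjusted over the list alone (camera adjusted p = 6.95e-13, adjusted p = 0.00104 with estimated correlation). Among them were its rate-limiting enzyme Cyp7a1 (-5.74 ± 0.72) and Cyp8b1 (-4.30 ± 0.59). Pericentral Wnt targets were lower, as 6 of 19 fell, 11 adjusted over the list alone (camera adjusted p = 2.82e-05, adjusted p = 0.293 with estimated correlation). They included Cyp2e1 (-3.13 ± 0.56) and Cyp1a2 (-3.07 ± 0.46). The cell cycle inhibitor Cdkn2b (6.83 ± 0.68) rose, while Ccne2 (-2.40 ± 0.63) and Tk1 (-1.59 ± 0.32) fell. Also macrophage (mean 0.76) genes were higher as a list (camera adjusted p = 0.0455, adjusted p = 0.67 with estimated correlation). In tumors H (n = 6) 2213 genes passed with at least a 2-fold change against two-week H livers (n = 6), 1225 higher and 988 lower.

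ERK pathway genes were higher in tumors HB too: 10 of 16 rose, 10 adjusted over the list alone (camera adjusted p = 6.78e-06, adjusted p = 0.104 with estimated correlation). Members included Il1rn (5.30 ± 0.83). The imprinted fetal genes Dlk1 (5.59 ± 1.15) and Igf2 (3.93 ± 0.74) rose. The symbols Tgfa (1.80 ± 0.40) and Ctnnb1 (0.88 ± 0.32), the latter at 0.88 (limma adjusted p = 0.0552) with the sex of the sample itself, rose. Ctnnb1 (0.76) did not pass and Tgfa stood at 1.10 without two-week HB replicate 2, and Ctnnb1 (0.76) did not pass without two-week HB replicate 4. In tumors HB (n = 6) 2826 genes passed with at least a 2-fold change against two-week HB livers (n = 4), 1816 higher and 1010 lower. Of them 64.3% were higher, against 51.3% with centring and 46.3% after quantile normalization. For tumors HB the median of all genes moved by -0.17 under centring and -0.16 under quantile normalization.

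Tumors labelled HT, which read high on the Myc probe, lost pericentral Wnt targets, of which 15 of 19 fell, 16 adjusted over the list alone (camera adjusted p = 2.92e-13, adjusted p = 0.0552 with estimated correlation). The largest included Tbx3 (-5.17 ± 0.74), Cyp2e1 (-4.84 ± 0.54) and Lgr5 (-4.61 ± 0.74). Cell cycle genes were higher, as 21 of 26 rose, 22 adjusted over the list alone (camera adjusted p = 9.99e-07, adjusted p = 0.458 with estimated correlation). These included the kinases Bub1b (3.56 ± 0.81) and Cdk1 (3.44 ± 0.93). The ERK targets Ccnd1 (-2.90 ± 0.42) and Dusp6 (-2.12 ± 0.39) fell (camera adjusted p = 0.0635). Also endothelial (mean -1.32) genes were lower as a list (camera adjusted p = 0.000234, adjusted p = 0.459 with estimated correlation), and neutrophil (mean 2.77) genes were higher as a list (camera adjusted p = 0.0465, adjusted p = 0.459 with estimated correlation). In tumors labelled HT (n = 6) 3766 genes passed with at least a 2-fold change against two-week HT livers (n = 6), 2157 higher and 1609 lower. Of these 57.3% were higher, against 36.5% after quantile normalization. For tumors labelled HT the median of all genes moved by -0.13 under centring and -0.23 under quantile normalization.

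Tumors M, with c-Myc alone, had nearly the whole cell cycle list raised, as 25 of 26 rose and 1 fell, 25 and 1 adjusted over the list alone (camera adjusted p = 2.55e-12, adjusted p = 0.118 with estimated correlation). Among them were topoisomerase Top2a (5.24 ± 0.84) and Mki67 (5.08 ± 0.51). Of the ribosome biogenesis and Myc target list 26 of 28 rose, 27 adjusted over the list alone (camera adjusted p = 4e-09, adjusted p = 0.12 with estimated correlation). They included Nop56 (2.21 ± 0.28) and Polr1a (2.10 ± 0.21). Beside them Wnt target (mean -1.47) and endothelial (mean -0.91) genes were lower as lists (camera adjusted p = 0.00228 and 0.0394, adjusted p = 0.437 and 0.61 with estimated correlation). In tumors M (n = 10) 4819 genes passed with at least a 2-fold change against two-week M livers (n = 6), 2506 higher and 2313 lower. Among these genes 52% were higher, against 35.5% after quantile normalization. For tumors M the median of all genes moved by -0.20 under quantile normalization.

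Tumors labelled MH read low on the Myc probe. Urea cycle genes were lower, as 16 of 17 fell, 16 adjusted over the list alone (camera adjusted p = 5.49e-06, adjusted p = 0.34 with estimated correlation). Passing members included Otc (-3.16 ± 0.43). Cell cycle genes Ccne2 (-2.94 ± 0.63) and Bub1b (-2.67 ± 0.91) fell and Ccne1 (1.64 ± 0.34) rose (camera adjusted p = 0.577). ERK targets Egr1 (2.48 ± 0.72) and Maff (2.83 ± 0.51) rose (camera adjusted p = 0.0527). In tumors labelled MH (n = 6) 6226 genes passed with at least a 2-fold change against two-week MH livers (n = 6), 2868 higher and 3358 lower. Thus 46.1% were higher, against 26.5% after quantile normalization. For tumors labelled MH the median of all genes moved by -0.11 under centring and -0.23 under quantile normalization and the count was 2742 with the array score as a term.

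Tumors T lost the whole periportal list, which holds urea and glucose synthesis around the portal vein: 14 of 14 fell, 14 adjusted over the list alone (camera adjusted p = 2.34e-21, adjusted p = 0.00124 with estimated correlation). The largest included Etnppl (-7.48 ± 0.63), Cyp2f2 (-5.83 ± 0.47) and the arginase Arg1 (-4.18 ± 0.53). Pericentral Wnt targets were higher, as 8 of 19 rose, 8 adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.51 with estimated correlation). These included Sp5 (2.65 ± 0.80) and Lgr5 (2.66 ± 0.76), the latter at 1.51 (limma adjusted p = 0.188) with the sex of the sample itself. Without tumor T replicate 2 Sp5 stood at 4.04 and the list mean at 2.05 in place of 1.30. Stress genes were higher, since 6 of 12 rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 2.95e-05, adjusted p = 0.0114 with estimated correlation). Among them were Asns (7.23 ± 0.54) and Trib3 (3.27 ± 0.51). The symbols Myc (2.16 ± 0.51) and Ctnnb1 (1.11 ± 0.30), the latter at 0.58 without tumor T replicate 3 (limma adjusted p = 0.136), rose while Tgfa stood at 0.75 ± 0.38 (adjusted p = 0.156). Beside them macrophage (mean -1.21) and endothelial (mean -0.89) genes were lower as lists (camera adjusted p = 0.00259 and 0.00695, adjusted p = 0.51 and 0.537 with estimated correlation). In tumors T (n = 6) 2441 genes passed with at least a 2-fold change against two-week T livers (n = 6), 1006 higher and 1435 lower.

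In tumors TM pericentral Wnt targets were lower, as 16 of 19 fell, 16 adjusted over the list alone (camera adjusted p = 5.11e-11, adjusted p = 0.0753 with estimated correlation). They included the glutamate transporter Slc1a2 (-5.43 ± 1.07) and Cyp2e1 (-4.13 ± 0.53). Cell cycle genes were higher: 19 of 26 rose, 20 adjusted over the list alone (camera adjusted p = 3.61e-09, adjusted p = 0.25 with estimated correlation). Members were Mki67 (3.74 ± 0.60) and Top2a (3.52 ± 0.94). In tumors TM (n = 6) 2596 genes passed with at least a 2-fold change against two-week TM livers (n = 6), 1307 higher and 1289 lower. That is, 50.3% were higher, against 28.6% after quantile normalization. For tumors TM the median of all genes moved by -0.11 under centring and -0.23 under quantile normalization.

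Tumors were also compared with one another in an additive model of the 4 oncogenes, which takes the labels of HT and MH as given. Its sex term is that of the recipient, while all 18 tumors with beta-catenin came from female donors. Beta-catenin changed few genes. Tmem63b (0.68 ± 0.13, adjusted p = 0.00947) and the X-inactivation transcript Xist (6.00 ± 0.90, adjusted p = 0.000189) rose, the latter also with c-Myc (7.63 ± 1.19) and H-ras (5.43 ± 1.06), and the dosage compensation gene Msl3 (-0.96 ± 0.16, adjusted p = 0.00179) fell. With the sex of the sample itself Xist stood at 1.94 (limma adjusted p = 0.112) and Msl3 at -0.48 (limma adjusted p = 0.172), and neither passed. Of the Wnt targets 0 of 17 passed in limma, 9 rose adjusted over the list alone, and at unadjusted p under 0.05 11 lay higher and 0 lower (camera adjusted p = 3.93e-09, adjusted p = 0.459 with estimated correlation), with values of 3.24 ± 1.09 for Slc1a2 and 2.16 ± 0.69 for Tbx3. Beside them fatty acid oxidation (mean 0.52) and plasma protein (mean 0.41) genes were higher as lists (camera adjusted p = 8.49e-06 and 0.000177, adjusted p = 0.4 and 0.577 with estimated correlation), and macrophage (mean -0.47) and stellate cell and fibroblast (mean -0.52) genes were lower as lists (camera adjusted p = 0.00299 and 0.00757, adjusted p = 0.632 and 0.632 with estimated correlation). The symbol Ctnnb1 stood at -0.05 ± 0.22 (adjusted p = 0.954). For beta-catenin (n = 58 tumors) 2 genes passed with at least a 2-fold change, 1 higher and 1 lower. For beta-catenin the count was 7 after quantile normalization, 13 with the sex of the sample itself, 4 with the intensity trend removed and 4 without the tumors labelled HT and MH.

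With c-Myc, periportal genes were higher, as 6 of 14 rose, 7 adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.975 with estimated correlation). Passing members included Sds (2.92 ± 0.72) and Etnppl (2.59 ± 0.83). Stress genes were lower: 6 of 12 fell, 8 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.268 with estimated correlation). The largest included Xbp1 (-1.56 ± 0.30) and Atf4 (-1.22 ± 0.22). Also Wnt target (mean -1.48) genes were lower as a list (camera adjusted p = 0.00482, adjusted p = 0.975 with estimated correlation). Tgfa (-1.16 ± 0.31) fell, and the brightest Myc probe stood at -0.89 ± 0.42 (adjusted p = 0.127). For c-Myc (n = 58 tumors) 1612 genes passed with at least a 2-fold change, 886 higher and 726 lower.

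H-ras went with higher plasma protein genes, of which 10 of 16 rose, 13 adjusted over the list alone (camera adjusted p = 6.41e-06, adjusted p = 0.57 with estimated correlation). Among them were albumin Alb (1.75 ± 0.39) and Apoc3 (1.97 ± 0.36). Beside them periportal (mean 1.66) genes were higher as a list (camera adjusted p = 4.46e-06, adjusted p = 0.57 with estimated correlation). Wnt targets were lower, as 7 of 17 fell, 12 adjusted over the list alone (camera adjusted p = 0.000167, adjusted p = 0.57 with estimated correlation). Members were Sp5 (-3.24 ± 0.86) and Lgr5 (-2.90 ± 0.78). For H-ras (n = 58 tumors) 1967 genes passed with at least a 2-fold change, 1181 higher and 786 lower. For H-ras the count was 1119 after quantile normalization, 1279 with the sex of the sample itself and 288 with the array score as a term.

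TGFalpha changed single genes, among them the peroxisomal oxidase Hao2 (3.1 ± 0.58), Tff3 (2.89 ± 0.69) and Anxa13 (3.87 ± 0.80), which rose, and the sterol acyltransferase Soat1 (-2.42 ± 0.68), which fell. Of the plasma proteins 1 of 16 rose, 12 adjusted over the list alone (camera adjusted p = 1.88e-07, adjusted p = 0.443 with estimated correlation), the member being Apoa1 (1.25 ± 0.34), which stood at 0.79 (limma adjusted p = 0.102) with the sex of the sample itself. Beside it macrophage (mean -0.74) genes were lower as a list (camera adjusted p = 0.00323, adjusted p = 0.495 with estimated correlation), not called without the tumors labelled HT and MH (mean 0.10, camera adjusted p = 0.98), and periportal (mean 0.90) genes were higher as a list (camera adjusted p = 0.000405, adjusted p = 0.495 with estimated correlation). For TGFalpha (n = 58 tumors) 211 genes passed with at least a 2-fold change, 158 higher and 53 lower. For TGFalpha the count was 319 with the sex of the sample itself, 126 with the array score as a term and 1288 without the tumors labelled HT and MH.

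Recipient sex was tested in the 24 tumors BM, BT, labelled MH, and TM, which all came from female donors. No gene passed in limma (0 of 15426), and 1346 lay at an unadjusted p under 0.05. The male-biased Cyp4a12a (0.94 ± 0.34) and Slco1a1 (1.28 ± 0.63) and the bile acid gene Akr1d1 (1.82 ± 0.55) had the largest values of their lists without passing. Of the bile acid list 0 of 17 passed in limma, 4 rose adjusted over the list alone, and at unadjusted p under 0.05 5 lay higher and 0 lower (camera adjusted p = 6.34e-05, adjusted p = 0.248 with estimated correlation). Also periportal (mean 0.75) and urea cycle (mean 0.53) genes were higher as lists (camera adjusted p = 3.86e-06 and 2.62e-05, adjusted p = 0.248 and 0.476 with estimated correlation), and ERK pathway (mean -0.59), cell cycle (mean -0.34) and endothelial (mean -0.43) genes were lower as lists (camera adjusted p = 3.86e-06, 0.00385 and 0.0215, adjusted p = 0.248, 0.777 and 0.777 with estimated correlation). Y-linked Kdm5d (1.67 ± 0.53) and Xist (-0.32 ± 0.37) did not pass either.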

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

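The tests chosen only after their result was seen were the scaling of the BT interaction, the array score for the TM and MH interactions, the Myc probe gap, the donor sex of the tumors labelled HT and MH and the genes that recurred in all 6 interactions.

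Interactions of 2 transgenes differed from the sum of the singles in 643 genes for TM, 474 for MH, 3088 for BT, 1070 for BM, 2869 for HB and 1709 for HT. Differences between arrays along the axis that varies within groups may be part of this. With the array score as a term counts fell to 1213 for BT, 905 for HT, 316 for BM and 46 for HB. The axis does not account for TM and MH, 2 whose counts stayed. Scaling stays open for BT, with 3390 genes after quantile normalization but the median moved by 0.33. Chance values of the shared control arrays are argued against for the genes of 1 sign in all 6, since 0 of 100 draws of unchanged groups had as many (244 on genes with a value in every array, highest draw 158). A joint action of the transgenes stays open, as does a difference of control from all two-week livers in something else, since 175 of the 244 lay opposite to control in all 10 groups, a share that draws also had (20.3 of 28.5).

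Tumors labelled HT and MH may have had their labels exchanged. On a score of c-Myc made without them and without Myc, 11 of their 12 arrays lay on the side opposite to their label, as did 2 of the other tumors, both TM. Scaling between arrays is argued against, since after quantile normalization the lowest HT lay 2.66 above the highest MH on the Myc probe, and with the axis score taken out 11 arrays stayed opposite. A raised Myc gene of the animal itself is argued against by the probe gap, outside the range of tumors T in 6 of 6 tumors labelled HT. Samples or values exchanged under labels that kept the donor sex are argued against, since sex-linked genes went against that sex in 0 of 12 (HT from males, MH from females), and an exchange that took the sex along stays open.

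The interferon list was lower across two-week livers. Chance values of the shared control arrays are argued against, since 1 of 100 simulated draws had as many comparisons lower. Left open are control replicate 6, without which 7 comparisons were lower, and scaling between arrays, with 5 lower after quantile normalization, since both numbers lie between the bounds set beforehand. A lasting difference between control and two-week animals, such as the marker transgene, could be a biological cause, and no group tests it.

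Single samples far from the rest of their group numbered 18 among 180 groups tested (20 groups and 9 measures), and chance gives about 1 in 20. On the cell cycle list tumor M replicate 5 lay at 0.482 and two-week BM replicate 1 lay at 2.115. On the ERK list tumor M replicate 9 lay at 1.591. On the interferon list tumor M replicate 9 lay at 1.462. On the fetal list tumor BT replicate 6 lay at 3.467, tumor MH replicate 6 lay at 3.508 and two-week HB replicate 2 lay at -0.554. On the pericentral Wnt list tumor BM replicate 3 lay at -1.324, tumor MH replicate 4 lay at 1.907 and tumor T replicate 2 lay at -2.575. For Ctnnb1 tumor MH replicate 3 lay at -2.019, tumor T replicate 3 lay at 3.508 and two-week BT replicate 5 lay at -2.065. For the Myc probe tumor H replicate 1 lay at 3.336, tumor M replicate 5 lay at 2.036, tumor TM replicate 5 lay at 2.199 and two-week MH replicate 6 lay at 2.229. For Tgfa two-week H replicate 1 lay at -0.476.

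Random splits, 100 per comparison, were fitted on genes with a value in every array. For two-week B, T, M and H as many genes came up in 1 of 100 splits, the real one, the fewest possible. Real counts against the highest other were B 380 against 317, T 389 against 252, M 230 against 194 and H 469 against 318. It was 3 of 100 for two-week BT (545 against 1129), 4 for BM (93 against 198) and 2 for HT (174 against 278). It was 9 for MH (79 against 390) and 5 for HB (599 against 1442), the real one included. Without correction over comparisons sharing controls, chance is excluded for none. For two-week TM the real count was 0 (highest other 812), so 100 of 100 had to give as many and nothing follows for chance. Other splits called more genes than the real one in all two-week pairs, and the cause was not tested. For every interaction the real split alone gave as many, with TM 683 against 179, MH 516 against 0, BT 3020 against 1432, BM 1147 against 18, HB 2739 against 929 and HT 1750 against 1. The same held for every tumor comparison, with BM 2683 against 1551, BT 2458 against 1423, H 1594 against 776, HB 1724 against 1046, HT 2567 against 1571, M 3172 against 1691, MH 4053 against 2673, T 1826 against 986 and TM 1660 against 1257 and tumors against control 1628 against 795. It held for sex in livers (207 against 0), beta-catenin (4 against 1), c-Myc (1069 against 62), H-ras (1380 against 2) and TGFalpha (188 against 184). Oncogene splits shuffled tumors, not groups, and cannot exclude chance between groups. Interaction splits shuffled control too and cannot exclude a control difference alone. Recipient sex gave 0 against 0 (100 of 100), which says nothing of chance.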

How the results depend on the processing

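The tests chosen only after the data were seen were those with the residual component, the array score, the intensity trend, control replicate 6, values beyond 16, the tumors labelled HT and MH, two-week BT replicate 5, tumor T replicates 2 and 3, and the arrays whose sex-linked genes went against the label. Of 451 counts under an alternative, 367 stayed within 1.5 times the count in the report and 84 moved further, and the cause was not tested. The replicate number as a block, equal weights, a robust prior with a trend, and values beyond 16 set to missing moved none of the counts they were run on by more than 1.5 times. Replicate numbers did not pair the samples: of 110 same-numbered pairs in 19 comparisons 29 had r above 0.1, with r from -0.636 to 0.401, and in 0 comparisons was every pair above it. How far signal over background limits these counts is not known, since only 1 array has scanner values.

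With each array centred on its median the counts that moved were two-week livers B 657 and M 115. After quantile normalization they were two-week livers B 1712, M 367, H 1053, TM 18, MH 795, BT 3, BM 352 and HB 5, then interactions MH 850 and BM 2489, then sex in livers 464, beta-catenin 7 and H-ras 1119. Fitting only the groups compared, without a sex term, gave two-week livers B 93, T 58, M 28, H 118, TM 0, MH 0, BT 1, BM 2, HB 0 and HT 3. Without a sex term in the full fit they were two-week livers TM 2 and BM 57. On probes with a value in every array, which are fewer genes, they were two-week livers TM 0 and MH 79, then tumors HB 1749, M 3186, labelled MH 4062 and TM 1665, then tumors against control 1640, beta-catenin 4 and c-Myc 1069. With only probes well above background in both channels of the scanned array, the moved count was two-week livers TM 3. With each gene as the mean of its probes they were two-week livers BT 319, BM 42, HB 373 and HT 93, then interactions MH 304. With the sex of the sample itself in place of that of the recipient they were beta-catenin 13, H-ras 1279 and TGFalpha 319.

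With the first principal component of the residuals as a term they were two-week livers B 635, M 421, TM 21, MH 366, BM 171, HB 1489 and HT 296, then interactions TM 1249, MH 761 and BM 1881. With the array score on the first gene axis of the residuals as a term they were two-week livers TM 15, MH 299, BT 282 and HB 71, then interactions BT 1213, BM 316, HB 46 and HT 905, then tumors labelled MH 2742, then H-ras 288 and TGFalpha 126. With the intensity trend of each array removed they were two-week livers TM 3 and MH 86, then beta-catenin 4. Without control replicate 6 they were two-week livers TM 10, MH 55, BT 327, BM 57, HB 356 and HT 62. With control replicate 6 turned like every other array, the moved count was two-week livers MH 62. Without the tumors labelled HT and MH they were beta-catenin 4 and TGFalpha 1288. The residual component is orthogonal to the groups by construction, so it lowers the residual spread and cannot test a difference along that axis between groups; the array score can.

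Leaving out each of the 4 two-week HB samples in turn gave 60 to 1909 genes against control, 1351 to 4358 for the HB interaction and 1924 to 3613 for tumors HB. Without two-week BT replicate 5, which holds many values beyond 16, 256 genes passed in two-week BT livers, and without two-week HT replicate 3, 214 in two-week HT livers.

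Of 3378 list results 3057 kept their direction and side of the threshold, 245 lost a call, 73 gained one and 3 turned. With the array score as a term those were the ribosome biogenesis and Myc target list for c-Myc in tumors to a mean of 0.43 (camera adjusted p = 0.0239) and the ERK list for H-ras in tumors to -0.39 (camera adjusted p = 0.0367), and without the tumors labelled HT and MH the stellate cell list for H-ras, at 1.34 (camera adjusted p = 0.0225). Of the calls given with a mean, those ended by other alternatives than leaving out control replicate 6 (number in brackets) were macrophage in TGFalpha (1), tumors H (1) and two-week TM (1), stellate cell and fibroblast in beta-catenin (2), sex in livers (1) and tumors BT (1), endothelial in the HB interaction (4), recipient sex (2), tumors M (4), tumors against control (2), two-week HT (5) and two-week TM (1), erythroid in sex in livers (1), lymphocyte in sex in livers (5) and tumors BT (2), neutrophil in tumors BM (4) and tumors labelled HT (3), biliary in two-week BM (6) and two-week TM (1). The axis was defined in livers, and tumor biology can lie along it. Of 2971 results for single named genes 2773 kept direction and side, 7 gained a call, 4 turned and the others lost a call. All 4 turned with each gene as the mean of its probes. Those were Ddx58 in the BM interaction at -0.54 (limma adjusted p = 0.714), Dhx58 in the HB interaction at -0.12 (limma adjusted p = 0.942), Fdps in the HB interaction at 0.52 (limma adjusted p = 0.395) and Dhx58 in two-week B livers at 0.0232 (limma adjusted p = 0.989), and the cause was not tested.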

Other observations

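The 3 lists in this paragraph were fixed before the data were examined and were chosen for description after their results were seen. Neutrophil genes were higher in tumors TM, where 4 of 4 rose, 4 adjusted over the list alone (camera adjusted p = 0.000112, adjusted p = 0.0613 with estimated correlation), with S100a8 (5.56 ± 0.96) and S100a9 (3.26 ± 0.76), and in tumors M, where 4 of 4 rose, 4 adjusted over the list alone (camera adjusted p = 0.00488, adjusted p = 0.141 with estimated correlation). Targets of NF-kB and chemokines were higher in tumors H, where 8 of 11 rose, 9 adjusted over the list alone (camera adjusted p = 3.18e-06, adjusted p = 0.0513 with estimated correlation), with Cxcl1 (3.38 ± 0.59) and Ccl2 (2.37 ± 0.57). The interferon list, lower in two-week livers, was higher in tumors H against two-week H livers, where 10 of 14 rose, 10 adjusted over the list alone (camera adjusted p = 7.57e-06, adjusted p = 0.11 with estimated correlation), with Cxcl10 (3.14 ± 0.70). No difference between these tumor groups was tested.

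Within livers, the first gene axis of the residuals held 21.3% of the residual spread, and control arrays lay on it by sex, with 3 males between -1.16 and -0.61 and 3 females between 0.38 and 0.85. The highest correlation of a pair of arrays within a group lay between 0.768 and 0.919, and no arrays were identical.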
